A study of Mus musculus with 4 samples.

How the data were processed

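Gene expression was measured in 4 clones of 15P-1, a mouse Sertoli cell line. Sertoli cells are the somatic cells of the testis that nurse the germ cells. Per the labels' protocols, every clone was stably transfected with a plasmid that expresses Rhox5, an X-linked homeobox gene, and was selected with the antibiotic G418. The labels put clones 6 and 24 in a high Rhox5 group and clones 14 and 16 in a low Rhox5 group, and the sample titles call them Rhox5-positive and Rhox5-negative. Total RNA of each clone was labelled with biotin by the standard Affymetrix procedure and hybridised to 1 array, per the labels' protocols. The series therefore held 4 arrays, 2 clones per group, no repeat array of any clone and no untransfected control. Clone and array cannot be separated, so p-values measured the spread between clones of a group together with the array error. The labels gave no hybridisation batch.

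The deposited table held 45101 probe sets and 4 columns of intensity signals on a linear scale. Per the submitters' processing notes, the signals were made with MAS5, which summarises the probes of a probe set and scales each array to a common level; no version was stated. All 4 arrays had almost the same trimmed mean, from which 2% of the values were left out at each end, so a global scaling was already in the deposited signals. The table held no detection calls, and the background correction of MAS5 could not be checked. The number of arrays limited the precision. The median signals were 218 in clone 6, 244.9 in clone 24, 195.2 in clone 14 and 285.1 in clone 16.

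All tests used log2(signal + 64), where the pseudocount of 64 was the 25th percentile of the table. Of the 45037 probe sets that are not controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed. Symbols were checked by Entrez gene number against a mouse RefSeq table of assembly GRCm38.p6. This matched 34741 of the 34945 probe sets and left 204 with the older annotation. No gene was named from a probe set with several symbols. The table named no genome build, so the RefSeq table supplied only symbols, chromosomes and the order of genes. Probe sets with a mean signal over the 4 arrays at or above the median of those means (lowest kept 235.5) were kept, which left 22519 probe sets, 19909 of them with 1 symbol, for 11030 genes. For values per gene, the probe set with the highest mean signal over all arrays stood for the gene.

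Differences between the 2 groups were tested per probe set with limma 3.58.1 in R 4.3.3 (two-sided, eBayes with a mean-variance trend, prior degrees of freedom 4.06, residual degrees of freedom 2). Adjusted p-values were Benjamini-Hochberg values over all 22519 probe sets, with a threshold of 0.05, and standard errors (SE) are limma's moderated ones. Differences are log2 values, high minus low. A second, descriptive count took the probe sets for which every high clone was at least 2-fold from every low clone in the same direction. A total of 27 gene lists was fixed, and the 24 with at least 5 members past the filter were tested with limma's camera (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists). Camera was repeated with a correlation estimated per list, and limma's fry was run beside it. That repeat of camera also bases its p-values on the 2 residual degrees of freedom. A call lost there cannot be put down to correlation between genes alone. The designs, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took Rhox5, the 14 genes with the greatest positive and the 14 with the greatest negative difference among genes past the threshold, filled from genes at least 2-fold apart in all 4 pairs of a high and a low clone, and up to 4 members of each tested list with the greatest absolute difference. Since no gene passed, all 14 in each direction were taken from the 2-fold genes. Rhox9, Rhox6, Rhox13, Fshr, Amh, Acta2, Des, Synpo2, Cnn1, Myh11, Cyp11a1, Cyp17a1, Cd14, Ptprc and Retn belong to the fixed lists but were named outside this rule, after their values were seen. Members of the androgen and insulin lists that are given only as not tested were named outside the rule too.

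The procedure was tested on simulated data: 20 runs over 22519 probe sets with the measured means and spreads and 200 changed probe sets per run. For the comparison of high with low clones, limma passed 0.2% of probe sets changed by 3 on the log2 scale and 4.5% of those changed by 5. The 2-fold rule found 79.9% of probe sets changed by 2 on the log2 scale, but also a mean of 442.6 unchanged ones per run. Camera called a list shifted by 1 on the log2 scale in 100% of runs. The simulated genes varied independently, which real genes do not. Each probe set's spread, measured on 2 residual degrees of freedom, was taken as the true one, and simulated values had no lower limit.

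Alternatives were pseudocounts of 1 and of the table's median, quantile normalization, median centring, no filter, a filter at the 75th percentile, other eBayes settings, an unmoderated test, means over all probe sets of a gene, fold thresholds of 1.5 and 3, an adjusted p of 0.1, and leaving out each clone in turn. Subtraction of each clone's median deviation per chromosome, and 1 probe set per gene for the 2-fold count, were added after seeing the data. Plots were drawn with matplotlib 3.10.9.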

Results

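The data were array signals from 4 clones of the 15P-1 Sertoli cell line, all stably transfected with a Rhox5 expression plasmid. Clones 6 and 24 had high Rhox5 mRNA and clones 14 and 16 had low Rhox5 mRNA, with 1 array per clone. The series title places the work in the study of androgen-induced Rhox homeobox genes and of genes under the control of the androgen receptor. The comparison asked which transcripts differ between Sertoli cells with much and with little Rhox5.

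Rhox5 gave signals of 10934.8 in clone 6 and 9029.6 in clone 24, against 319.5 in clone 14 and 123 in clone 16. The difference was 5.22 ± 0.49 on the log2 scale (SE, n = 2 clones per group). The clones had been chosen by their Rhox5 mRNA, so this value checks the labels and is not an independent result. Rhox5 itself had an adjusted p of 0.44, and without clone 24 its difference was 5.36. Of the other Rhox genes on the array, Rhox9 had signals of 157.8, 145.1, 262.1 and 80.8 in clones 6, 24, 14 and 16, and neither it nor Rhox6 or Rhox13 passed the filter on low signals.

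Tmem47 codes for a membrane protein of cell junctions. Its brighter probe set had signals of 3204.7 and 2210.6 in clones 6 and 24, and of 8.9 and 4.9 in clones 14 and 16, a difference of 5.27 ± 0.48 (SE, n = 2 per group, adjusted p = 0.44). A second probe set of Tmem47 gave 1234.2 and 1105.4 against 81.5 and 57.5, a difference of 3.21. Where signals lay below the pseudocount of 64, it set the size of the difference: for the brighter probe set of Tmem47 the value was 8.44 with a pseudocount of 1 and 3.59 with 234, the table's median. Slc6a15, a transporter of neutral amino acids, had 733 and 1105.7 against 22.5 and 14.6 (3.55 ± 0.55, adjusted p = 0.972). The extracellular superoxide dismutase Sod3 had 1037.2 and 960.7 against 51.5 and 21.5 (3.42 ± 0.52, adjusted p = 0.972). The surface glycoprotein gene Cd24a had 9224.1 and 12665.6 against 2554.2 in clone 14 and 211.6 in clone 16, a difference of 3.68 ± 1.02 that was 5.30 without clone 14 and 2.05 without clone 16. Fhl1, a LIM domain protein of muscle, had a difference of 3.01 ± 0.69. Ccn2, the connective tissue growth factor, had 39117.6 and 14419.8 against 3643.5 and 5687.5. The other named genes in this direction were Ndn (3.21), Plcl2 (3.05), Endod1 (2.73), Gpr149 (2.69), Dnajc22 (2.58), Tenm4 (2.53) and Gstk1 (2.5). In all 7 clone 6 stood above clone 24, with 2295.8 and 299.6 for Plcl2 and 1975 and 234.6 for Gpr149, and without clone 6 the differences were 1.39 for Ndn, 1.70 for Plcl2, 1.64 for Endod1, 1.30 for Gpr149, 1.62 for Dnajc22, 1.59 for Tenm4 and 1.91 for Gstk1. For Ndn, clone 6 at 26159.8 stood far above clone 24 at 2044.5, and its probe set belongs to a class that can pick up related sequences. None of its 4 other probe sets past the filter had the opposite sign. Without clone 24 the Ndn difference was 5.02.

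Among the named genes with lower signals in the high Rhox5 clones, Cpxm1, a carboxypeptidase-like secreted protein, had 1131.1 and 1385.7 against 7882.7 and 13467.5 (−2.98 ± 0.44, SE, n = 2 per group, adjusted p = 0.972). Podxl2, a sialomucin, had 7.8 and 17.1 against 1207.6 and 689.2 (−3.68 ± 0.58, and −6.18 with a pseudocount of 1 and −2.23 with 234). The lactate exporter Slc16a3 had 30.8 and 104.3 against 1632.4 and 489 (−2.94 ± 0.72). Pth1r, the receptor of parathyroid hormone, had a difference of −3.36 ± 0.80, and Pygl, a glycogen phosphorylase, −2.97 ± 0.71 (−4.59 with a pseudocount of 1 and −1.93 with 234). In many of these genes clone 6 stood far below clone 24. Crip1 had 150.5 in clone 6 and 6084.2 in clone 24, against 36961 and 28854.2 in the low clones (−4.83 ± 1.44). Ifitm1, an interferon-induced membrane protein, had 202.2 and 10171 against 39731.3 and 22970.3 (−4.20 ± 1.57), and the secreted Wnt antagonist Sfrp1 had 754.2 and 6216.8 against 15541.6 and 21327.9 (−3.01 ± 0.93). Larp6 (−3.63), Auts2 (−3.33), Rnf144a (−3.16), Smarca1 (−3.06), Gda (−3.06) and Gfra2 (−2.98) completed the 14. Of the 27 genes named for size in either direction beside Rhox5, 16 had differences more than 1.5 times smaller without clone 6, among them Crip1 (−2.41), Ifitm1 (−1.56) and Sfrp1 (−1.54). Without clone 24, with clone 6 as the only high clone, the differences were −7.25 for Crip1, −6.83 for Ifitm1, −5.56 for Larp6, −4.62 for Gfra2 and −4.48 for Sfrp1. For Auts2, 1 of 3 other probe sets had the opposite sign. The Gfra2 probe set can also pick up related sequences, but none of 4 other Gfra2 probe sets past the filter had the opposite sign.

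**Figure D1:**
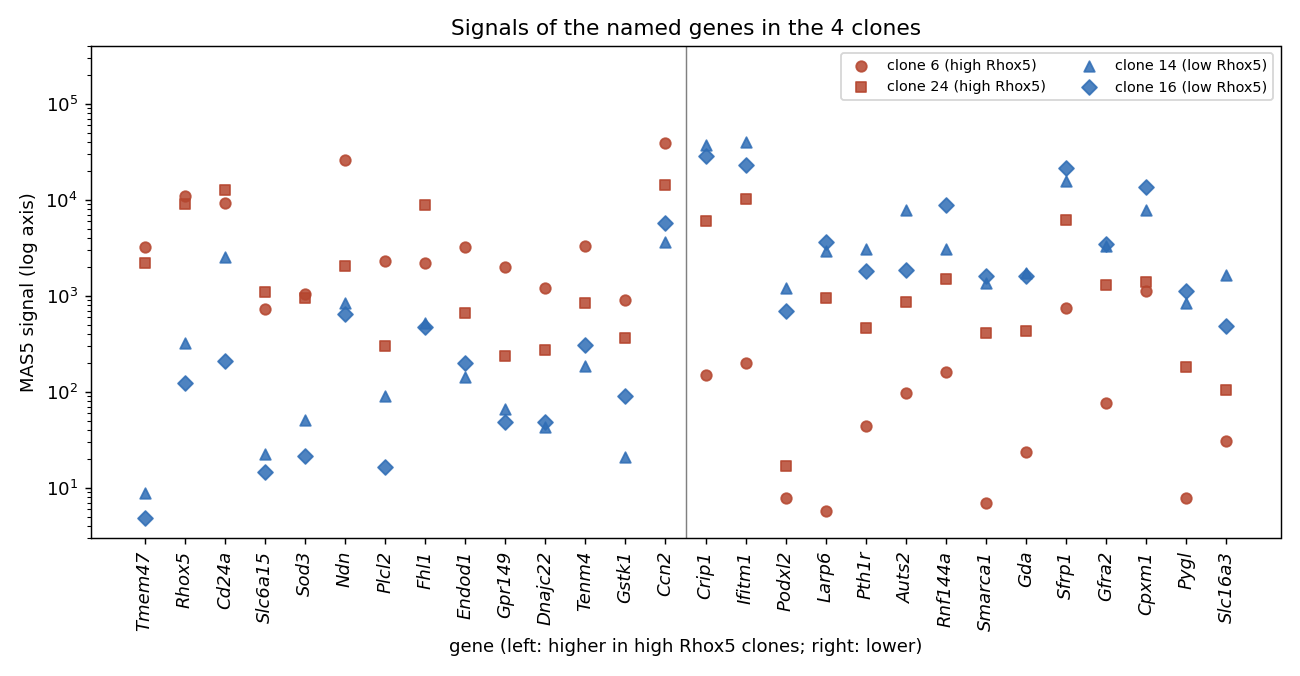
Array signals (log axis) of the 14 named genes higher and the 14 lower in the high Rhox5 clones, 1 symbol per clone, with high clones 6 and 24 in red and low clones 14 and 16 in blue. Rhox5 lies at 10934.8 and 9029.6 in the high clones and at 319.5 and 123 in the low clones, and for Crip1 clone 6 (150.5) lies well below clone 24 (6084.2).

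Counted over all genes, limma passed 0 of 22519 probe sets at an adjusted p of 0.05, and the lowest adjusted p was 0.44. At an unadjusted p under 0.05 there were 892 probe sets, 440 higher and 452 lower in the high clones, and the unmoderated test also passed 0. A total of 258 probe sets was at least 2-fold apart in all 4 pairs of a high and a low clone, 138 higher and 120 lower, and with 1 probe set per gene 131 genes were, 56 higher and 75 lower. Simulated clones gave a mean of 442.6 such probe sets among the unchanged ones, and the measured 258 lay below this. The simulation took each spread, measured on 2 residual degrees of freedom, as the true one and set no lower limit on signals. Both can raise the simulated count, so the comparison cannot decide whether 258 exceeds what the spread between clones gives. The groups did not overlap at 33.6% of the probe sets, where chance gives 33.3%. Fits that leave out a clone have 1 clone in a group, so their p-values hold no spread of that group.

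Clones of the same group differed from each other as much as clones of different groups. Clones 6 and 24 correlated at r = 0.895 across probe sets, which are not independent replicates, and 17.3% of the probe sets were at least 2-fold apart. Clones 14 and 16 correlated at r = 0.877 with 25.8% at least 2-fold apart. Between groups, the most similar pair was clones 24 and 16 (r = 0.913, 15.5%) and the least similar was clones 6 and 16 (r = 0.849, 26.7%). The array of clone 14 had a 3' to 5' signal ratio of 3.45 for beta-actin, against 1.25, 1.18 and 1.28 in clones 6, 24 and 16, and of 1.42 for Gapdh, against 0.95, 0.8 and 0.8. Ratios of the Dap control RNA were 19.75 in clone 14 and 6.23, 4.21 and 5.05 in the others. Those of the Lys, Phe and Thr control RNAs were 9.54, 7.71 and 7.77 in clone 14, and at most 5.74, 2.53 and 4.83 in the others. The array of clone 14, a low Rhox5 clone, thus stood apart in these ratios. For beta-actin and Gapdh they follow RNA quality and labelling. Control RNAs do not come from the cells, so their ratios do not measure the quality of the cells' RNA.

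The 4 clones were also parted in the other possible ways. The split of clones 6 and 14 from clones 24 and 16 had 712 probe sets at least 2-fold apart, 631 of them lower in clones 6 and 14. The split of clones 6 and 16 from clones 24 and 14 had 175. With 1 probe set per gene the counts were closer together, at 131 genes for the split by Rhox5 group, 159 for clones 6 and 14 and 97 for clones 6 and 16. At the preset correlation, camera called 6 lists for the split by Rhox5 group. It called 9 for clones 6 and 14 and 5 for clones 6 and 16, so list calls were not particular to the Rhox5 grouping.

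**Figure D2:**
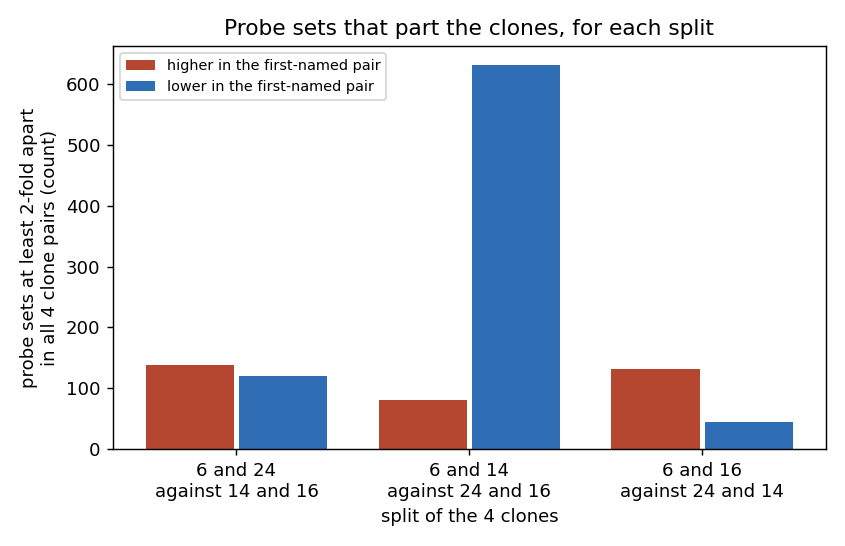
Number of probe sets at least 2-fold apart in all 4 clone pairs for each of the 3 ways to split the 4 clones, with red bars for probe sets higher and blue bars for those lower in the first-named clones. The split by Rhox5 group has 138 and 120, and the split of clones 6 and 14 from clones 24 and 16 has 81 and 631.

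Cell cycle genes had higher signals in the high Rhox5 group, with 33 of 35 tested members higher and a median difference of 1.162 (camera adjusted p = 3.08e-12, and adjusted p = 0.596 with an estimated correlation). Cdc6, which licenses replication origins, had 3234.9 and 4039.2 in clones 6 and 24, against 2059.5 and 306 in clones 14 and 16 (2.05 ± 0.82, SE, n = 2 per group). Cyclin E2 (Ccne2) had 2896.1 and 5853.8 against 1895.4 and 479.3. The mitotic kinesin Kif20a had 7914.3 and 6929.9 against 3435.7 and 1268.3. The replicative helicase subunit Mcm5 had 24454.5 and 34715.4 against 24525.7 and 3027.3. Measured against the mean of the high clones, the list's median was −2.10 in clone 16 and −0.06 in clone 14. The median difference was 2.10 without clone 14, and without clone 16 it was 0.06 with an adjusted p of 0.0518. No member passed the test over all genes or adjusted over the list alone. The list of cell cycle inhibitors and p53 targets had 11 of 20 members higher (median 0.22, adjusted p = 0.253, and 0.0428 without clone 6), among them Plk2 with 23312.2 and 14081.3 against 9389.6 and 5999.6.

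Genes of collagens and extracellular matrix had lower signals in the high Rhox5 group, with 33 of 45 members lower and a median difference of −0.60 (camera adjusted p = 3.25e-06, and adjusted p = 0.596 with an estimated correlation). For 23 of them both high clones lay below both low clones, and for 3 above. Thrombospondin 2 (Thbs2) had 12279.2 and 15047.6 in clones 6 and 24, against 28981.7 and 67314.3 in clones 14 and 16 (−1.70 ± 0.46). The laminin chain gene Lama4 had 1000 and 6877.7 against 16384.6 and 19161.2 (−2.71 ± 0.86). For the gelatinase Mmp2, clone 6 alone was low, at 140.2, against 11508.2, 10584.9 and 18062.9. Col11a1, a fibrillar collagen chain, had 116.2 and 2575.7 against 894.5 and 8743.2. The list stayed past the threshold when any of the 4 clones was left out, with medians from −0.81 to −0.44, but limma passed none of its members, over all genes or adjusted over the list alone. Without clone 24 the difference of Mmp2 was −6.09, with clone 6 as the only high clone.

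The list of cytoskeletal genes and targets of the transcription factor SRF was called higher, with 18 of 28 members higher and a median difference of 0.20 (camera adjusted p = 0.0103, and adjusted p = 0.596 with an estimated correlation). The median was 0.11 without clone 6 (adjusted p = 0.0428), 0.43 without clone 24 (0.00507), 0.39 without clone 14 (0.0165) and 0.07 without clone 16 (0.0475). It was 0.40 with probe sets averaged per gene (0.00783). Its members with the greatest differences went both ways. Ccn2 (2.37 ± 0.56), the immediate early gene Fos (2.00 ± 0.78) and Ankrd1 (1.51 ± 0.68), a nuclear mechanical stress protein, were higher, and the leiomodin gene Lmod1 was lower (−1.87 ± 0.88). In Ccn2 and Ankrd1 clone 6 was highest, and in Fos clone 24, with 3477.8 against 818.6, 613.5 and 224.5 in clones 6, 14 and 16.

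The list of insulin and IGF signalling and adipokines had 19 of 22 tested members lower and a median difference of −0.70 (camera adjusted p = 0.00654, and adjusted p = 0.596 with an estimated correlation). Retn was the only adipokine gene tested and was higher (0.72 ± 0.55). The insulin genes Ins1 and Ins2 and the adipokine genes Adipoq and Lep were not among the tested members. The examples with the greatest differences were low in clone 6 alone. The receptor adaptor Grb14 had 18.2 in clone 6 and 4430.8, 5109.9 and 5759.3 in clones 24, 14 and 16. Igfbp7, an IGF-binding protein, had 342 in clone 6 and 17319.9, 14915.9 and 17152.7 in the others, and the adipogenic receptor Pparg had 82.1 and 1516 against 1088.2 and 3345.4. Igfbp3 had 922.7 and 13931 against 5596 and 30470.6. Without clone 24 the differences were −6.06 for Grb14 and −5.31 for Igfbp7. Without clone 6 the list's median was −0.23 (adjusted p = 0.41), and without clone 16 it was −0.47 (adjusted p = 0.277). With probe sets averaged per gene it was −0.41 (adjusted p = 0.00783).

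Apoptosis genes had 19 of 23 members lower and a median difference of −0.22 (camera adjusted p = 0.022, and adjusted p = 0.596 with an estimated correlation). Both pro-apoptotic and protective genes were among them: Bmf (−1.40 ± 0.53) and Bcl2l11 (−1.28 ± 0.61) code for killers of the BH3-only class, and Birc3 (−0.93 ± 0.43) for an inhibitor of apoptosis. The call ended without clone 6 and without clone 16, though the medians there, −0.21 and −0.26, were close to that with all clones. The median was −0.40 without clone 24 and −0.13 after chromosome medians were subtracted (camera adjusted p = 0.0317, an alternative added after seeing the data). Ribosomal protein genes had 32 of 34 members lower and a median of −0.35 (camera adjusted p = 2.81e-06, and adjusted p = 0.596 with an estimated correlation), for example Rps24 with 67211.7 and 73373.6 against 87948.7 and 124610.2. After quantile normalization their median was −0.04 and the camera adjusted p was 0.603. The median was −0.27 without clone 24, where the call ended, and −0.23 without clone 16.

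**Figure D3:**
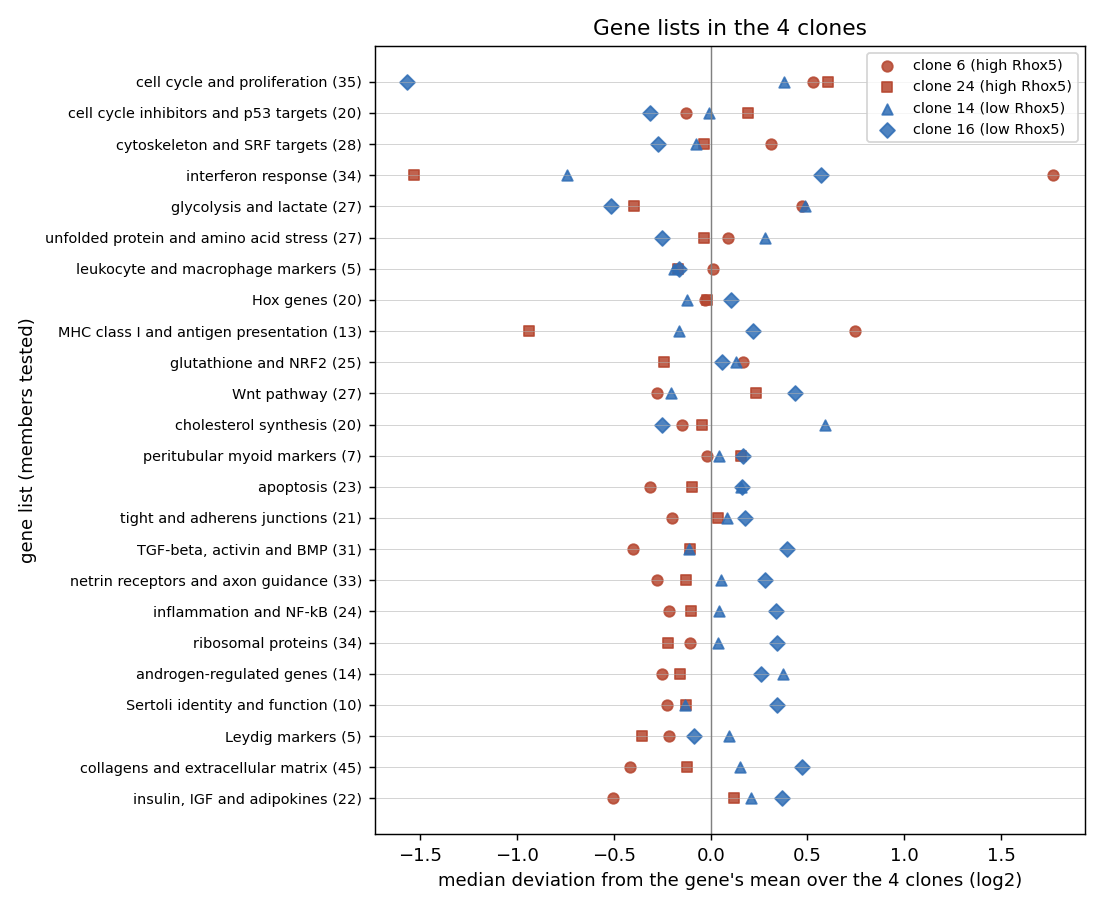
Median deviation of each tested gene list from the genes' means over the 4 clones (log2 axis), 1 symbol per clone, with high clones 6 and 24 in red, low clones 14 and 16 in blue, and lists ordered by their median difference between the groups. For the cell cycle list clone 16 lies at −1.57 while the other 3 clones lie at 0.53, 0.60 and 0.38, and for the interferon list the high clones lie apart at 1.77 and −1.53.

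The fixed list of androgen-regulated genes, a theme of the series title, had 11 of 14 tested members lower and a median difference of −0.42 (camera adjusted p = 0.071). The list has 25 members, and those not tested include the androgen receptor gene Ar, Drd4, Eppin, Tsx, Cldn3 and Cldn11. Klf9, a steroid-responsive zinc finger factor, had 4596.6 and 8711.7 in clones 6 and 24, against 16089.9 and 21492.1 in clones 14 and 16 (−1.54 ± 0.44, SE, n = 2 per group). The glucocorticoid-induced leucine zipper gene Tsc22d3 had 1681.4 and 3411.6 against 4822.9 and 4560.6 (−0.95 ± 0.47), and Igf1r −0.77 ± 0.43. Steap4, a metalloreductase, was low in clone 6 alone (8 against 2320, 1867.4 and 4105.8), and its difference was −5.30 without clone 24. The list passed the threshold with the stricter filter (adjusted p = 0.0315), with no filter (0.0384) and after chromosome medians were subtracted (0.0341), the last an alternative added after seeing the data.

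Netrin receptors and other axon guidance genes had 24 of 33 members lower and a median of −0.29 (camera adjusted p = 0.0974). The netrin receptor Unc5c had 281.4 and 375.5 in the high clones, against 887.6 and 1512.5 in the low clones (−1.65 ± 0.47, adjusted p = 0.972). Its second probe set had 156.3 and 27 in clones 6 and 24, against 223.7 in clone 14 and 1150.8 in clone 16 (−2.06). There clone 14 lay near clone 6. For the ligands and other members of the list, values were as follows. The Unc5c ligand gene Ntn1 had 236.2 in clone 6 and 2998.2, 4876.8 and 4048.7 in the others, with 1 other probe set of the opposite sign. Efnb2, an ephrin ligand, had a higher signal (2.05 ± 0.82), and Sema5a had 2651.6 and 749.4 against 508 and 631. The list was called with no filter (adjusted p = 0.0384), without clone 14 (0.0165) and after chromosome medians were subtracted (0.045).

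Sertoli cell genes had 9 of 10 tested members lower and a median of −0.51 (camera adjusted p = 0.113), with a median of 0.05 without clone 16 and a call without clone 14 (−0.72, adjusted p = 0.00903). The transcription factor gene Gata4 had 8.9 in clone 6 and 661.9, 523.8 and 884.3 in clones 24, 14 and 16. Gdnf, a growth factor for spermatogonial stem cells, had 121.9 and 746.3 against 1254.2 and 694.6 (−1.37 ± 0.78). Inhbb had a difference of −1.12 ± 0.63, and for Clu the value was −0.80 ± 1.15. Of 30 Sertoli genes on the array only 10 passed the filter, and neither Fshr, the receptor of follicle-stimulating hormone (144.9, 130.2, 107.6 and 25.5), nor Amh, a hormone of immature Sertoli cells (58.3, 13.2, 21.1 and 47.3), was among them.

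Among inflammation genes, 15 of 24 members were lower (median −0.32, camera adjusted p = 0.172), and 2 passed when adjusted over the list alone. These were Saa3, an acute phase apolipoprotein, with 4108 and 3151.5 against 20592.3 and 15844.9 (−2.31 ± 0.38), and Ptgs2, the inducible prostaglandin synthase, with 22436 and 11046.3 against 3690.9 and 3113.1 (2.19 ± 0.46). Over all genes both had an adjusted p of 0.972. The chemokine gene Cxcl5 had 94.1 in clone 6 and 14782, 28408.7 and 56369.1 in clones 24, 14 and 16, and its difference was −7.99 without clone 24. The list was called without clone 6 (adjusted p = 0.00543) and with the stricter filter (0.0355). No other list had a member that passed adjusted over the list alone, except that Rhox5 was the only tested member of the Rhox list. In the TGF-beta, activin and BMP list (21 of 31 lower, median −0.28, adjusted p = 0.113), the activin subunit gene Inhba had 6281.2 and 1893.7 against 797.5 and 570.5 (2.25 ± 0.63). Wnt pathway genes had 16 of 27 members lower (median −0.16, adjusted p = 0.509), and Dkk2, a secreted Wnt antagonist, had 9824.6 and 724.1 against 281.2 and 469.5. Both lists were called lower at the preset correlation with the stricter filter (medians −0.37 and −1.15, camera adjusted p = 0.0355 for each). They were also called lower without clone 24 (medians −0.51 and −0.32) and without clone 14 (−0.50 and −0.59). With all 4 clones the correlation was estimated at 0.105 for the TGF-beta list and 0.394 for the Wnt list, and the adjusted p with it was 0.749 and 0.961.

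Camera gave no call for the remaining tested lists. They were glycolysis and lactate (15 of 27 higher, 0.12, adjusted p = 0.898), cholesterol synthesis (11 of 20 lower, −0.20, adjusted p = 0.546), unfolded protein and amino acid stress (17 of 27 higher, 0.12, adjusted p = 0.763), tight and adherens junctions (11 of 21 lower, −0.23, adjusted p = 0.858), Hox genes (10 of 20 higher, 0.02, adjusted p = 0.636) and glutathione and NRF2 targets (15 of 25 lower, −0.14, adjusted p = 0.509). For glycolysis the mean, at −0.07, had the opposite sign to the median. Interferon response genes had 19 of 34 members higher (0.14, adjusted p = 0.342) and MHC class I genes 7 of 13 lower (−0.12, adjusted p = 0.898). Camera called 3 of these lists in opposite directions with different clones left out, at the preset correlation of 0.01. With all 4 clones the correlation was estimated at 0.898 for interferon, 0.918 for MHC class I and 0.623 for glycolysis genes, and the adjusted p with it was 0.961, 0.976 and 0.976. With clones left out, camera called interferon genes lower without clone 6 (adjusted p = 1.88e-18) and higher without clone 24 (2.82e-22) or clone 16 (0.00276), and MHC class I genes lower without clone 6 (1.06e-06) and higher without clone 24 (0.000411). Glycolysis genes were called lower without clone 6 (0.00682) or clone 16 (0.0237) and higher without clone 14 (0.0183). Cholesterol synthesis genes were called lower without clone 16 (0.00176), and unfolded protein genes higher without clone 14 (0.017), where the correlations estimated with all 4 clones were 0.547 and 0.195 and the adjusted p with them 0.961 for each. With an estimated correlation no tested list in this report had an adjusted p under 0.596. These values also rest on 2 residual degrees of freedom and do not measure the effect of correlation alone. For androgen-regulated genes the estimate was −0.0749, below the preset 0.01. Even so, the camera p there was 0.133 against 0.0207 at the preset correlation.

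Markers of other testis cells gave no call either. Leydig cell markers had 3 of 5 tested members lower (median −0.57, adjusted p = 0.636). Of the steroidogenic genes, Star passed the filter (341.9, 306.3, 506.6 and 572.8 in clones 6, 24, 14 and 16), and Cyp11a1 and Cyp17a1 did not. Peritubular myoid markers had 4 of 7 lower (median −0.21, adjusted p = 0.898, with a test statistic of the opposite sign), and Acta2, the smooth muscle actin, was high in every clone (52182.1, 74830.4, 58790.7 and 88734.7). Des, Synpo2, Cnn1 and Myh11 of the same list did not pass the filter. Leukocyte markers had 3 of 5 higher (median 0.11, adjusted p = 0.618, and 0.0384 with no filter). Only 2 of 25 germ cell markers and 4 of 15 endothelial markers passed the filter, so these lists were not tested.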

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

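Settings that subtract chromosome medians or take 1 probe set per gene were chosen after seeing the data. With all 4 clones, limma passed 0 probe sets under each alternative run, and Rhox5 differed by 4.52 to 5.64 without passing the threshold. The named genes kept their direction in all 906 values computed on all 4 clones, but much of this was fixed beforehand: filters and eBayes settings leave a difference as it is, and the order of clones that are 2-fold apart in all pairs stays the same with any pseudocount. Of 27 genes named for size beside Rhox5, the difference was more than 1.5 times larger for 5 with a pseudocount of 1 and more than 1.5 times smaller for 7 with the table's median, since their low signals lie under or near the pseudocount. With so few clones a missed threshold says little about stability: limma passed 4.5% of simulated differences of 5 on the log2 scale. That share holds for the simulation's spreads, which can differ from the real ones. Array background limits the low signals, and detection calls were not used here. No paired analysis was possible because the groups share no clone number.

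The count of 258 probe sets at least 2-fold apart in all pairs became 1088 at 1.5-fold, 55 at 3-fold, 131 with 1 probe set per gene (56 higher, 75 lower), 154 with the table's median as pseudocount, 642 with no filter and 116 with the stricter filter; thresholds and filters act on such counts by construction. Its split of 138 higher and 120 lower became 122 and 141 after median centring, 164 and 100 after subtraction of chromosome medians, and 69 and 47 with the stricter filter. The 6 list calls became 0 with an estimated correlation, 0 with fry and 10 with the stricter filter; the cause of the last was not tested. With quantile normalization the ribosomal list lost its call. Uncalled lists whose median changed sign were peritubular myoid markers (0.12 with quantile normalization, 0.28 with no filter, 0.02 with probe sets averaged per gene), tight and adherens junctions (0.24 with no filter, 0.21 with probe sets averaged), Hox genes (−0.01 with no filter, −0.22 with the stricter filter) and the interferon response (−0.01 with the stricter filter). The causes were not tested.

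Leaving out each clone in turn, where the lone clone of a group is assumed to vary like the other group's, gave Rhox5 differences from 4.70 to 5.74, with an adjusted p under the threshold (0.0397) only without clone 24, as for 12 other named genes. The number of probe sets passed by limma ranged from 0 to 37, the 37 without clone 24. The 2-fold count ranged from 916 without clone 6 to 2091 without clone 24, with fewer pairs to satisfy, and its higher and lower parts were 474 and 442 without clone 6, 715 and 1376 without clone 24, 1037 and 939 without clone 14, and 1579 and 447 without clone 16. The lists called ranged from 6 without clone 16 to 12 without clone 14. List medians that crossed 0 ranged from −0.72 to 0.05 for Sertoli genes, −0.50 to 0.52 for glycolysis, −0.67 to 0.26 for cholesterol synthesis, −0.41 to 0.24 for unfolded protein stress, −1.33 to 1.84 for the interferon response, −0.98 to 0.69 for MHC class I, −0.24 to 0.12 for junctions, −0.59 to 0.16 for the Wnt pathway, −0.06 to 0.21 for Hox genes, −0.56 to 0.03 for glutathione, −0.32 to 0.09 for peritubular myoid markers and −0.06 to 0.18 for leukocyte markers. Of the 27 genes named for size, which had to differ in every pair and so could not change sign here, 16 had differences more than 1.5 times smaller without clone 6 and 1 without clone 16, and 6 had larger ones without clone 24. Named list members that crossed 0 were Clu (−2.41 to 0.80), Igfbp7 (−5.31 to 0.11), Igfbp3 (−3.74 to 0.09), Shmt2 (−0.41 to 2.01), Oas1a (−0.40 to 5.93), Oas3 (−0.21 to 4.02), Oas2 (−0.98 to 4.36), H2-D1 (−0.66 to 2.78), Psmb10 (−0.35 to 1.39), H2-M3 (−1.15 to 0.31), Cxcl12 (−4.95 to 0.03), Cdh11 (−3.90 to 0.51), Cdh13 (−3.18 to 0.85), Sfrp2 (−5.29 to 1.83), Gpx7 (−0.30 to 4.66), Cd68 (−0.03 to 2.23), Csf1r (−0.58 to 1.34) and Adgre1 (−0.73 to 0.12). Single clones set these directions; why they differ was not tested.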

Other observations

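The tests of explanations in this part were chosen after the results were seen. Interferon response genes differed more within the groups than between them. Their median deviation from the mean over the 4 clones was 1.77 in clone 6, −1.53 in clone 24, −0.74 in clone 14 and 0.57 in clone 16 (34 members). The antiviral synthetase gene Oas1a had a signal of 13122.2 in clone 6 and 100.2, 180.8 and 128.4 in clones 24, 14 and 16, and its difference was 5.93 without clone 24. Oas2 had 5463.2, 72.3, 116.9 and 337.5, and Oas3 had 1926.4, 42.1, 31.2 and 94.2. For MHC class I and antigen presentation genes the medians in clones 6, 24, 14 and 16 were 0.75, −0.94, −0.16 and 0.22, and H2-D1 had 28609.7, 2579.6, 2702.2 and 6216.6. The immunoproteasome subunit gene Psmb8 had 2100, 387.2, 1931.3 and 3489.3. Of 16 leukocyte markers, 5 passed the filter. Cd68 (1188.6, 198, 192.6 and 214.9) and Csf1r (1995.6, 482.7, 751.5 and 753.3) were highest in clone 6 as well. The others were not: Adgre1 (338.3, 330.1, 302.6 and 598.6) was highest in clone 16, Laptm5 (277.8, 312.4, 251.6 and 287.3) in clone 24 and Cd14 (1746, 1674.8, 1990.4 and 1537.2) in clone 14. Ptprc, which did not pass the filter, had 50.7, 100.1, 62.6 and 16.5. Without clone 6 the interferon list's median difference between the groups was −1.33, and without clone 24 it was 1.84.

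The higher signals of cell cycle genes in the high Rhox5 group rested on clone 16. Clone 14 lay −0.06 from the mean of the high clones on the log2 scale (interquartile range −0.40 to 0.13), and clone 16 lay −2.10 from it, which fits a low level in clone 16 alone. With a graded response, Rhox5 level as the whole cause would place clone 14 below both high clones. Only 15 of 35 members lay there in clone 14, against 32 in clone 16. Of the low clones, clone 14 had the higher Rhox5 signal (319.5 against 123), so the test cannot decide on a response already full at that level. A signal-dependent bias of the clone 16 array is argued against by the list's deviation of −1.57 there, outside the range of −0.45 to 0.36 of 10000 random lists matched on signal. The growth state of the cultures at harvest stays open and was not measured in these data.

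The split of clones 6 and 14 from clones 24 and 16 gave 712 probe sets at least 2-fold apart, against 258 for the split by Rhox5 group, but 159 genes against 131 when the brightest probe set stood for each gene. In all, 2 of the 3 splits reached 258 probe sets or more, and with 3 splits the share cannot go under 0.05. Array scaling as the whole cause is argued against by quantile normalization, which left 581 probe sets against 260, and low signals alone by the share of probe sets lower in clones 6 and 14, which fell with signal but in each of 5 equal ranges of signal rank was at least 2.56 times as high for probe sets that are not the brightest of their gene. Uneven labelling along the transcript cannot be told apart from real differences: 466 of the 631 probe sets lower in clones 6 and 14 were not the brightest of their gene, and 7.3% of the brightest probe sets of the same genes were 2-fold apart the same way. All 8879 probe sets past the filter that are not the brightest of their gene were compared with the brightest ones at matched signal. Their deviation minus that of the brightest ones was −0.24 in clone 14, whose 3' to 5' ratios were highest. It was 0.12 in clone 24 and 0.14 in clone 16, but 0 in clone 6. The design gives no biological explanation for this split.

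Genes of 6 chromosomes, placed by the GRCm38.p6 table, shifted together in single clones by more than the largest deviation in 1000 shuffles of genes over chromosomes (0.17, exceeded before rounding). The median deviation was 0.42 in clone 6 and −0.32 in clone 24 for chromosome 18 (283 genes), 0.32 in clone 6 for chromosome 10 (541 genes), 0.25 in clone 24 for chromosome 8 (600 genes), −0.18 in clone 6 for chromosome X, and −0.17 in clone 24 for chromosomes 12 and 16. Signal-dependent array bias is argued against because all 7 shifts lay outside 2000 gene sets matched on signal. A few co-regulated genes could not move a median over 283 or more genes, so the next count does not test them. It shows only how far the shifts ran along the chromosomes. All 10 of 10 consecutive blocks along each chromosome lay on the side of the shift. The weakest was a block of chromosome 8 with a median of 0 against −0.01 over all genes of clone 24. Rhox5 level as the whole cause is argued against for chromosomes 10, 12, 16, 18 and X, where clone 6 minus clone 24 was 0.39, 0.31, 0.30, 0.75 and −0.33 (largest of 1000 shuffles 0.15) and the shifts of clones 6 and 24 against the mean of the low clones were 0.40 and 0.01, 0.04 and −0.21, 0.04 and −0.22, 0.42 and −0.26, and −0.21 and 0.15, but it stays open as a part for chromosome 8 (0.17 and 0.38). Clone 6 minus clone 24 also passed 0.15 for chromosomes 1, 4, 6, 14 and 17 (−0.25, −0.20, −0.18, −0.19 and 0.17). The shuffles took genes as independent, which can make their limits too narrow. A difference in chromosome copy number between the clones is a candidate explanation for shifts of up to 0.42 spread along whole chromosomes, and no DNA was measured here.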
